A study of Mus musculus with 6 samples.

How the data were processed

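Photoreceptor RNA was measured in 6 libraries, each from 2 retinas of 1 mouse that carries SpCas9 in all cells. An adeno-associated virus with a photoreceptor-directed human GRK1 promoter driving the red protein mCherry was injected under the retina with a guide RNA against Nr2e3 or a control guide. About 100000 mCherry-positive cells per sample were sorted 6 months later. The labels disagree on the age at injection, which is postnatal day 21 in the series text and 4 weeks in the treatment protocol. Per the labels' protocols, RNA was extracted with Trizol and amplified with a SMARTer Ultra Low kit, which does not mark the strand of the RNA.

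The deposited values are raw read counts per gene symbol, 1 table per library, with 49997 genes and 5 entries that name no gene. Per the submitters' processing notes, the tools included cutadapt, STAR 2.7.3a, HTSeq 0.12.4 and DESeq2 1.42.0 with the mouse build GRCm38 (mm10). The gene annotation and the strand setting of the counting are not given in the sources used here. All 49997 names matched RefSeq genes of GRCm38.p6, from which the coordinates are taken, and exon overlaps come from GENCODE M21. The entries without a gene held 21.6 to 23.7% of all counts and were left out of library sizes and tests. They comprise counts in no feature (13.6 to 17.6%), ambiguous counts (1.84 to 2.01%) and counts of reads with several alignments (4.23 to 6.25%). Genes that share exons or near-identical copies can therefore lose or exchange reads, and a gene cannot be told apart from an antisense partner.

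Depth after this step was 24705561 to 34286248 gene counts per library, so that 3 counts correspond to 0.0802 to 0.131 CPM, the count scaled by the normalised library size. Such limits cover counting error only, since the reads carry no molecular identifiers. The 3 libraries of each group come from separate animals. Guide replicate 1 is male, guide replicates 2 and 3 are female, and all 3 control animals are male. A chi-square comparison of counts within each group found no pair of libraries close enough to be a single library deposited in duplicate. Guide libraries were not compared with control libraries in this way. Replicate numbers name different animals and were not used as pairs in the main test.

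Groups were compared with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr by group (min.count 10, which must be reached in about as many libraries as a group holds, not in each library, and 15 counts in total), glmQLFit and glmQLFTest with group as the only term, and Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values in the results come from this edgeR test unless another tool is named. CPM values are given as mean ± SD over the 3 libraries of a group, and a log2 fold change is guide over control with its standard error (SE), computed as the fold change divided by the square root of the quasi-likelihood F statistic.

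Lists of genes were fixed before the data were examined, 32 in all, covering rod and cone genes, photoreceptor structure, energy metabolism, ribosomes, clock and stress responses, markers of other retinal and blood-borne cell types, and sex-linked genes. Each was summarised by its members past the threshold, over all genes tested and adjusted over the list alone, and 30 were planned for a set test with camera (limma 3.58.1, preset correlation 0.01), adjusted over these lists. The sex-linked list served only to check labels. The pattern fixed for mitochondrially encoded mRNAs matched no name in these data. The 13 names used there, 12 of them tested in the main fit, were supplied after the data were seen, and that list was kept out of the adjustment. The tests were repeated with camera's estimated correlation and with fry. Under the DESeq2 and limma-voom settings, lists were tested with camera's pre-ranked form, on signed z-scores made from the p-values.

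The rule for naming genes was also fixed in advance. It takes Nr2e3, then up to 12 called genes per direction with the largest fold change, a mean of at least 5 CPM and no overlap between groups, leaving out Y-linked and sex-linked genes, unnamed transcripts and pseudogenes. In each list it takes up to 4 called members or, with none, up to 2 members of the highest level. With under 5 eligible genes in a direction, it takes the 5 of smallest p. Other genes named were chosen after their values were seen. Values of 2 genes that the rule takes are not reported here.

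Other settings chosen in advance were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no count filter, a mean of at least 5 CPM, the replicate number as a block, sex as a term, males only, each library left out in turn, library size without the 50 most abundant genes, adjusted p thresholds of 0.01 and 0.1, and a test against a 1.5-fold change. Settings added after seeing the data were a term for the replicate-3 libraries, leaving both of them out, robust estimation, and DESeq2 with sex as a term or on males. No control animal is female, so with sex as a term the guide effect compares guide replicate 1 with the male controls, as on males.

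The tests were checked on counts simulated from these libraries with 17138 genes, of which 100 were changed 2-fold and 100 changed 4-fold. A further 20 genes were raised 1.5-fold to check camera and were not counted among the unchanged genes. In that simulation of guide against control, edgeR recovered 7% of the 2-fold and 51% of the 4-fold changes, with 7 unchanged genes among 65 calls. DESeq2 recovered 21% and 67%, with 52 unchanged genes among 140 calls, and limma-voom 7% and 48%, with 4 among 59. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, and mean list levels use log2(CPM + 0.1).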

Results

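RNA of sorted mCherry-positive photoreceptors was counted in 3 libraries labelled Nr2e3 guide (below, guide libraries) and 3 labelled control guide (control libraries), 1 mouse each. Total gene counts ran from 24705561 to 33098812 in guide and from 32626751 to 34286248 in control libraries. Mitochondrially encoded transcripts took 1.27 to 2.75%, with the lowest shares in guide replicate 3 (1.31%) and control replicate 3 (1.27%).

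The comparison asks how photoreceptors differ 6 months after delivery of a guide against Nr2e3, which encodes a nuclear receptor of rods known to repress cone genes. Nr2e3 itself (GRCm38 chromosome 9, 59942771 to 59960834) was at 2081 ± 169 CPM in guide and 1612 ± 129 CPM in control libraries, a log2 fold change of 0.37 (SE 0.13, edgeR adjusted p = 0.716), with each guide library above each control library. Counts over the whole gene do not read insertions or deletions, so this level does not check the labels. Gm7616, a non-coding gene within the Nr2e3 span on the opposite strand (chromosome 9, 59951296 to 59952403), rose from 2.32 ± 0.999 to 15.7 ± 3.47 CPM (log2 fold change 2.76, SE 0.40, adjusted p = 0.0481, n = 3 each). It was chosen after its values were seen, and without strand its reads cannot be separated from introns of Nr2e3.

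Of 17138 genes tested, 54 rose and 5 fell in guide libraries, and 976 had an unadjusted p under 0.05. Genes almost silent in controls gave the largest rises, led by Htr5a, a serotonin receptor (chromosome 5, 27841716 to 27855086), which went from 0.206 ± 0.255 to 32.0 ± 2.05 CPM (log2 fold change 7.27, SE 0.82, adjusted p = 0.0175, n = 3 each). Itpr3, a calcium release channel of the endoplasmic reticulum (chromosome 17, 27057002 to 27122223), rose from 0.116 ± 0.150 to 17.4 ± 6.43 CPM (log2 fold change 7.18, SE 0.78, adjusted p = 0.0153), with 1, 10 and 1 counts in the control libraries. Igfbp2, which binds insulin-like growth factors (chromosome 1, 72824480 to 72852474), rose from 0.943 ± 0.405 to 72.9 ± 15.5 CPM, or 77.1-fold (log2 SE 0.37, adjusted p = 0.00115). Kdm1b, a histone demethylase (chromosome 13, 47043373 to 47085279), had the smallest p and rose from 8.53 ± 1.35 to 192 ± 35.9 CPM (22.5-fold, log2 SE 0.21, adjusted p = 0.000949).

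The other 8 of the 12 largest rises among eligible genes were Flvcr2, a membrane transporter (73.8-fold), Ccdc175 (70.2-fold), Ppef1, an EF-hand protein phosphatase (59.9-fold), Fyb2 (47.1-fold), Tmem164 (22.4-fold), Dzank1 (15.8-fold), Srl, a calcium-binding protein (14.8-fold), and Adrb1, the beta-1 adrenergic receptor (13.6-fold). Their adjusted p ran from 0.00115 for Ppef1 to 0.0373 for Fyb2. Among genes already abundant in controls, Car2, a carbonic anhydrase, rose from 689 ± 61.2 to 3414 ± 595 CPM (log2 fold change 2.31, SE 0.17, adjusted p = 0.0036). Elovl2, an elongase of very long fatty acids, rose from 140 ± 26.6 to 514 ± 101 CPM (log2 fold change 1.88, SE 0.20, adjusted p = 0.0157). Car2 and Elovl2 were chosen after their values were seen.

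Tmem116 fell from 28.5 ± 7.06 to 6.45 ± 0.587 CPM (log2 fold change -2.14, SE 0.24, adjusted p = 0.0163), Cd52, a lymphocyte surface glycoprotein, from 27.7 ± 5.74 to 8.82 ± 1.09 CPM (-1.65, SE 0.22, adjusted p = 0.0373), and Camk1g, a calmodulin-dependent kinase, from 26.4 ± 2.08 to 10.1 ± 1.51 CPM (-1.39, SE 0.20, adjusted p = 0.0468). H4c9, a histone gene (-2.73, adjusted p = 0.028), and the non-coding Gm35878 (-2.36, adjusted p = 0.0343) also fell and were chosen after their values were seen. Zfp607b (-1.13, adjusted p = 0.0542) and Tcp11 (-1.22, adjusted p = 0.0678) were next by p and did not pass.

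By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 33 of the rises were at least 4-fold and 51 at least 2-fold. Over all tested genes, groups did not overlap for 12.1%, against 10% by chance. Exons of 20 called genes overlap another gene, 18 of them on the opposite strand, including Kdm1b with Dek, Ccdc175 with Jkamp, Itpr3 with Itpr3os, Tmem116 with Erp29 and Cd52 with Crybg2, so part of their reads may belong to the partner. A further 7 called genes, H4c9 and Gm35878 among them, are not in GENCODE M21 and were not checked for exon overlap. Fits without guide replicate 1, 2 or 3 called 16, 21 or 17 genes higher and 4, 0 or 0 lower, with 14, 21 and 17 of the 59 called again. The fit without guide replicate 1 sets female guide animals against male controls. Its 4 lower genes were all Y-linked (Ddx3y, Eif2s3y, Kdm5d and Uty), and Xist was among its higher genes. Without control replicate 1 or 2 they called 14 or 15 higher and 0 lower, and without control replicate 3 80 higher and 9 lower. With sex as a term, where the effect rests on guide replicate 1 against the male controls, 6 genes were higher and 0 lower by edgeR. DESeq2 with that term called 125 higher and 147 lower. Among males, with 1 guide library, 0 passed by edgeR (1752 at unadjusted p under 0.05), and DESeq2 called 103 higher and 119 lower.

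**Figure D1:**
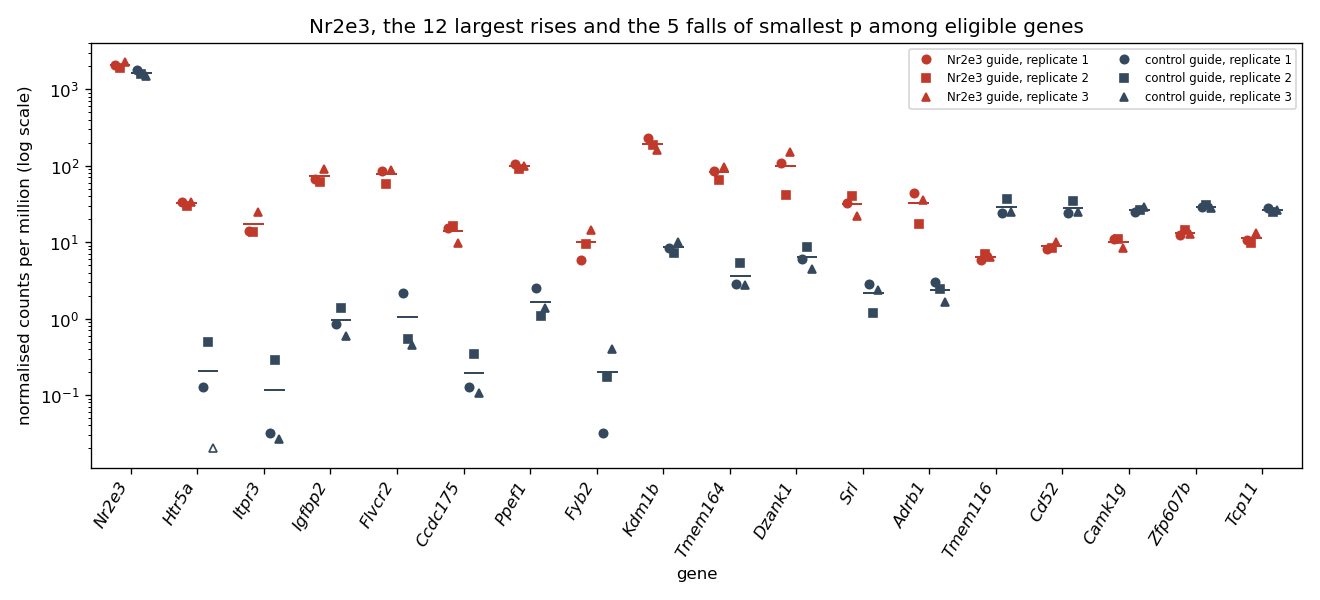
Normalised read counts in CPM (log scale) in each library for Nr2e3 and, among genes eligible under the naming rule, the 12 largest rises and the 5 falls of smallest p, with a marker per replicate, red for guide and grey-blue for control, and a bar at each group mean. Open markers are values under 0.02 CPM drawn at that level; Htr5a has means of 32.0 and 0.206 CPM, and Zfp607b and Tcp11 did not pass the test.

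Among the 11 cone phototransduction genes, Gnat2 and Pde6c stood at several times their control level while the opsins did not. Gnat2, the cone transducin alpha subunit (chromosome 3, 108086788 to 108101432), was at 7612 ± 708 CPM in guide and 772 ± 512 CPM in control libraries (log2 fold change 3.30, SE 0.61, adjusted p = 0.121, n = 3 each). Pde6c, the cone phosphodiesterase, was at 1058 ± 152 and 153 ± 86.3 CPM (log2 fold change 2.79, SE 0.48, adjusted p = 0.0898). Pde6h, its inhibitory subunit, had a log2 fold change of 1.97 (SE 0.69, adjusted p = 0.684) and Gnb3, the cone transducin beta subunit, 0.44 (SE 0.35, adjusted p = 0.995). The cone opsins Opn1sw (-0.83, SE 0.66) and Opn1mw (-0.66, SE 0.52) and the cone arrestin Arr3 (-0.36, SE 0.44) had adjusted p = 0.995 each. Without control replicate 3 they were at -1.32, -1.08 and -0.75 (adjusted p = 0.259, 0.276 and 0.310).

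By edgeR, 0 of these 11 passed over all genes (3 at unadjusted p under 0.05), while DESeq2 and limma-voom each called 2 higher. Adjusted over the list alone, 2 were higher, Gnat2 and Pde6c, each with adjusted p = 0.00413. The list's median log2 fold change was -0.65 and its mean 0.34, and camera gave direction up with adjusted p = 0.107, so median and test differ in sign. Fry's test for change in either direction gave adjusted p = 0.00443 and its test for 1 direction 0.957. In control replicate 3, 10 of the 11 genes lay below both other controls (median log2 ratio -2.04) and Gnb3 above them. Without control replicate 3, edgeR called Gnat2 (log2 fold change 2.83, adjusted p = 0.000797), Pde6c (2.38, adjusted p = 0.00303) and Gnb3 (1.02, adjusted p = 0.0215). Over 21 alternative settings, the adjusted p of Gnat2 ran from 4.82e-08 to 0.529 and passed in 7, that of Pde6c from 5.62e-08 to 0.529 and passed in 8, that of Gnb3 passed in 2 and that of Pde6h in 1. DESeq2 with sex as a term, where the effect rests on guide replicate 1, called Gnat2 (adjusted p = 0.00158) and Pde6c (0.00167), whereas edgeR with that term did not (0.430 and 0.380). With both replicate-3 libraries left out, edgeR also called Pde6h (1.74, adjusted p = 0.0156).

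Of 14 other cone-enriched genes, Smug1, a DNA repair glycosylase, rose from 60.6 ± 19.9 to 245 ± 65.4 CPM (log2 fold change 2.02, SE 0.29, adjusted p = 0.0468, n = 3 each), and the remaining 13 did not pass. Adjusted over the list alone, 2 were higher, Smug1 and Pygm, the muscle-type glycogen phosphorylase, at 822 ± 88.5 against 317 ± 110 CPM (log2 fold change 1.38, SE 0.24, adjusted p = 0.107 over all genes). The list median was -0.68 and camera's adjusted p 0.923. Control replicate 3 lay below both other controls in 10 of the 14 genes. Without it Smug1 had adjusted p = 0.0147 and Pygm, Ccdc136 (log2 fold change -1.42) and Ece1 (-1.53) also passed, while leaving out any other single library gave Smug1 an adjusted p of 0.0694 to 0.251 (4.04-fold in all 6).

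**Figure D2:**
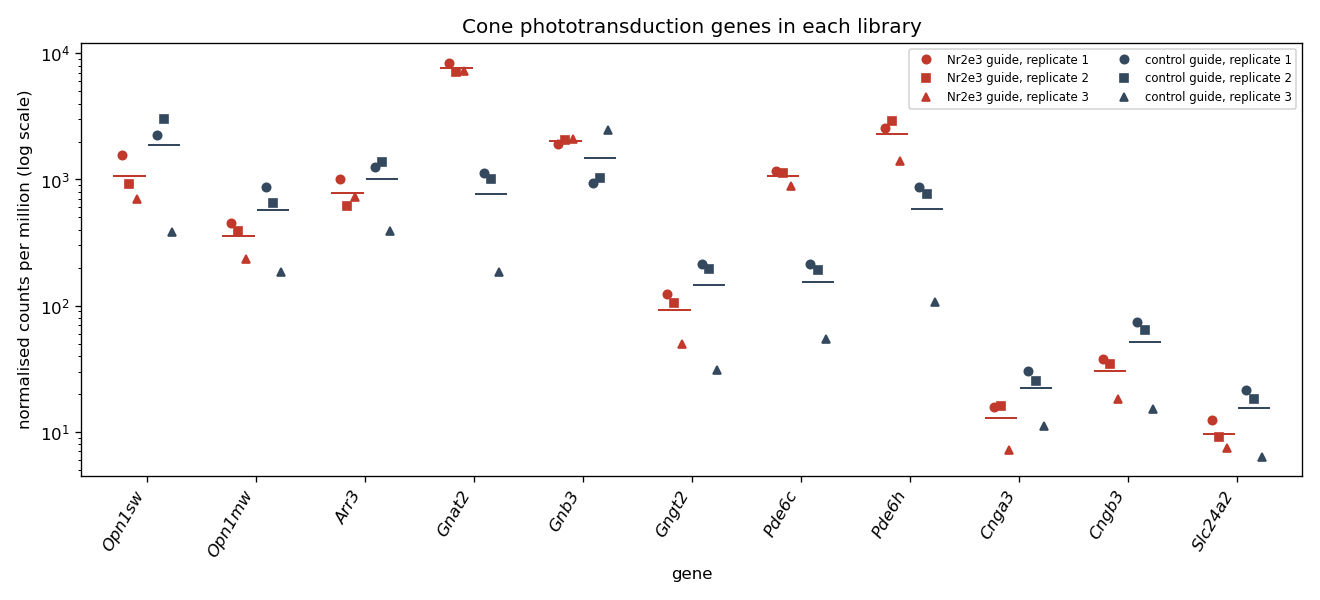
Normalised read counts in CPM (log scale) of the 11 cone phototransduction genes in each library, with a marker per replicate, red for guide and grey-blue for control, and a bar at each group mean. Gnat2 and Pde6c have guide means of 7612 and 1058 CPM and control means of 772 and 153 CPM; control replicate 3 (triangles) is the lowest control in 10 of the 11 genes.

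Rod genes differed little. Gnb1, the rod transducin beta subunit, had a log2 fold change of 0.18 (SE 0.15, adjusted p = 0.995). Of the 10 rod phototransduction genes, 0 passed by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05 (median 0.13). Of 13 other rod-enriched genes, 0 passed by any of these tools and 3 had an unadjusted p under 0.05 (median 0.03), with Sag, the rod arrestin, at 0.04 (SE 0.14) and Rom1, a disc rim protein, at 0.03 (SE 0.14).

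Of 24 genes shared by rods and cones, 0 passed by edgeR or limma-voom, 1 by DESeq2, and 5 had an unadjusted p under 0.05. Among them Rcvrn, the calcium sensor recoverin, had a log2 fold change of 0.48 (SE 0.19, adjusted p = 0.823) and Prph2, a disc rim protein, -0.01 (SE 0.13). Of 21 photoreceptor transcription factors, 0 passed by the 3 tools and 4 had an unadjusted p under 0.05, with Crx at -0.03 (SE 0.12) and Neurod1 at -0.20 (SE 0.18). Of 22 ribbon synapse genes, 0 passed by edgeR (2 at unadjusted p under 0.05) and 1 by DESeq2 and by limma-voom. Adjusted over the list alone, Lrit3, a synaptic adhesion protein, was higher (58.1 ± 9.41 against 27.5 ± 3.25 CPM, log2 fold change 1.08, SE 0.18), and fry's test for change in either direction gave adjusted p = 0.0101, whereas Cplx4 (-0.12, SE 0.13) and Snap25 (-0.12, SE 0.15) did not pass. Of 25 genes of outer segment discs and the connecting cilium and 8 visual cycle genes, 0 passed by the 3 tools, with 2 of each list at unadjusted p under 0.05. Rdh12, a retinol dehydrogenase, had a log2 fold change of -0.25 (SE 0.19) and Rbp3, the retinoid-binding protein of the matrix, -0.05 (SE 0.48).

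Energy metabolism lists held no called gene by edgeR. Of 22 genes of glycolysis and lactate transport, 0 passed by edgeR or DESeq2, 1 by limma-voom, and 5 had an unadjusted p under 0.05, with Pkm at -0.07 (SE 0.13) and Aldoa at 0.06 (SE 0.15). Of 80 nuclear genes of oxidative phosphorylation and 78 of cytosolic ribosomal proteins, 0 passed by the 3 tools and 0 had an unadjusted p under 0.05, with Ndufa4 at 0.38 (SE 0.38), Atp5a1 at -0.24 (SE 0.13), Rpl4 at 0.08 (SE 0.21) and Rpl3 at -0.01 (SE 0.22). Camera with its preset correlation placed both lists up (medians 0.15 and 0.14, adjusted p = 0.0363 and 0.0299). Both had adjusted p = 0.940 with an estimated correlation and 0.957 with fry's test for 1 direction. In control replicate 3, 75 of the 80 and 78 of the 78 genes lay below both other controls, and both list means were negative without it (-0.05 and -0.10) and without guide replicate 2 (-0.03 and -0.0019). Of 12 mitochondrially encoded mRNAs, 0 passed by the 3 tools and 0 had an unadjusted p under 0.05 (median 0.30), with CYTB at 0.18 (SE 0.32) and COX1 at 0.14 (SE 0.44).

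Stress and signalling lists held few called genes. Of 22 interferon response and antigen presentation genes, 1 passed by edgeR, by DESeq2, by limma-voom and adjusted over the list alone, and the list median was -0.15. Of 15 photoreceptor injury genes, 16 of the unfolded protein and integrated stress response, 13 p53 targets and 16 clock genes, 0 passed by the 3 tools and 0 had an unadjusted p under 0.05. Edn2, an endothelin of stressed photoreceptors, was at 16.7 ± 13.9 against 45.5 ± 72.2 CPM and Stat3 at 36.2 ± 9.99 against 52.2 ± 45.8 CPM. The injury list mean of -0.49 became -2.92 with sex as a term (camera adjusted p = 0.0138), which compares guide replicate 1 with the male controls, and 1.43 without control replicate 3 (0.0479). Guide replicate 1 had the lowest mean injury level and control replicate 3 the highest (0.509 and 3.48). Hspa5 (0.13, SE 0.15), Atf4 (-0.18, SE 0.21), Sesn1 (-0.08, SE 0.18), Ccng1 (0.04, SE 0.24), Bhlhe41 (0.27, SE 0.13) and Nr1d1 (-0.24, SE 0.24) lay near 0. Of 14 immediate early and dissociation genes, 0 passed by the 3 tools and 4 had an unadjusted p under 0.05, with Btg2 at -0.43 (SE 0.13), Ier3 at -0.33 (SE 0.13) and a camera adjusted p of 0.0736.

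Amacrine markers (12 genes, median log2 fold change -0.62) and pigment epithelium markers (6 genes, median -2.28) had 0 members past the threshold by edgeR or limma-voom, 1 lower each by DESeq2 and 1 each at unadjusted p under 0.05. Slc6a9, a glycine transporter of amacrine cells, was at 71.4 ± 45.0 against 106 ± 12.9 CPM, and Calb2, calretinin, at 49.6 ± 34.5 against 76.5 ± 53.4 CPM. Rdh5, a retinol dehydrogenase of pigment epithelium, was at 1.03 ± 0.568 against 3.78 ± 1.14 CPM (lower adjusted over the list alone), and Dct, a melanin synthesis enzyme, at 0.744 ± 0.650 against 4.86 ± 4.29 CPM. Camera placed both lists down with adjusted p = 0.0299, with adjusted p = 0.940 with an estimated correlation and 0.957 with fry's test for 1 direction. In control replicate 3, 12 of the 12 amacrine genes and 5 of the 6 pigment epithelium genes lay below both other controls. The exception was Rdh5, at 5.08 CPM there against 2.92 and 3.35 CPM in control replicates 1 and 2. Exons of Rdh5 overlap Bloc1s1 on the same strand, so part of its reads may belong to that gene.

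Of 13 microglia markers, 0 passed by the 3 tools and 0 had an unadjusted p under 0.05, with C1qb at 27.1 ± 16.7 against 36.8 ± 48.0 CPM and Ctss at 37.8 ± 28.2 against 31.4 ± 40.3 CPM. The list median was -0.33 while camera's direction was up (adjusted p = 0.710), and camera called the list up with limma-voom (mean 1.07, adjusted p = 0.00813), without control replicate 3 (1.80, 6.39e-06) and without guide replicate 1 (0.28, 0.0397). These calls use the preset correlation of 0.01, whereas the correlation estimated among these markers was 0.889. With the estimated value, camera's adjusted p in the main fit was 0.940, and these calls were not repeated with it. Guide replicate 1 had a list mean of 0.955, near control replicates 1 and 2 (0.826 and 0.936). In control replicate 3, 13 of the 13 microglia markers lay above both other controls (median log2 ratio 3.24), as did 11 of the 15 injury genes (median 2.86). The lists of Muller glia (15 genes), astrocytes (4), bipolar cells (16), horizontal cells (4), ganglion cells (8), infiltrating leukocytes (7), vascular cells (5) and red blood cells (5) had 0 members past the threshold by the 3 tools and 0 at unadjusted p under 0.05. Among Muller glia markers, Clu was at 822 ± 245 against 523 ± 359 CPM (log2 fold change 0.65, SE 0.45) and Aldoc at 473 ± 82.7 against 569 ± 82.1 CPM (-0.27, SE 0.18). The Muller glia list mean of -0.25 (camera adjusted p = 0.304) became -1.20 with sex as a term (0.0138) and -1.22 on males, both resting on guide replicate 1. It was -0.51 with limma-voom (0.0230), -0.64 without guide replicate 3 (0.00702) and -0.31 without control replicate 3 (0.0479). The leading members of the other lists had log2 fold changes from -2.26 (SE 1.52) for Gja1 of astrocytes to 0.81 (SE 0.50) for Gfap, with Scgn of bipolar cells at -1.12 (SE 0.54), Lrtm1 at 0.17 (SE 0.41), Calb1 of horizontal cells at 0.71 (SE 0.76), Prox1 at -0.40 (SE 0.53), Nefl of ganglion cells at -0.34 (SE 0.47) and Nefh at 0.03 (SE 0.34). Cd74 of leukocytes was at 0.40 (SE 0.52), Lyz2 at 0.10 (SE 0.48), Rgs5 of vascular cells at 0.33 (SE 0.48), Kdr at 0.16 (SE 0.52), Hba-a1 of red blood cells at -0.47 (SE 1.11) and Hbb-bs at -0.07 (SE 1.09). Of 4 crystallins, 0 passed by the 3 tools and 1 had an unadjusted p under 0.05. With no count filter, 14 were tested, 5 were higher and camera's adjusted p was 2.39e-08. Without guide replicate 2, with the filter, 5 were tested, 0 passed and camera's adjusted p was 0.886. Cryba1, at 3.89 ± 5.49 against 0.0722 ± 0.0804 CPM, was higher adjusted over the list alone, and Cryab had a log2 fold change of -0.02 (SE 0.47).

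**Figure D3:**
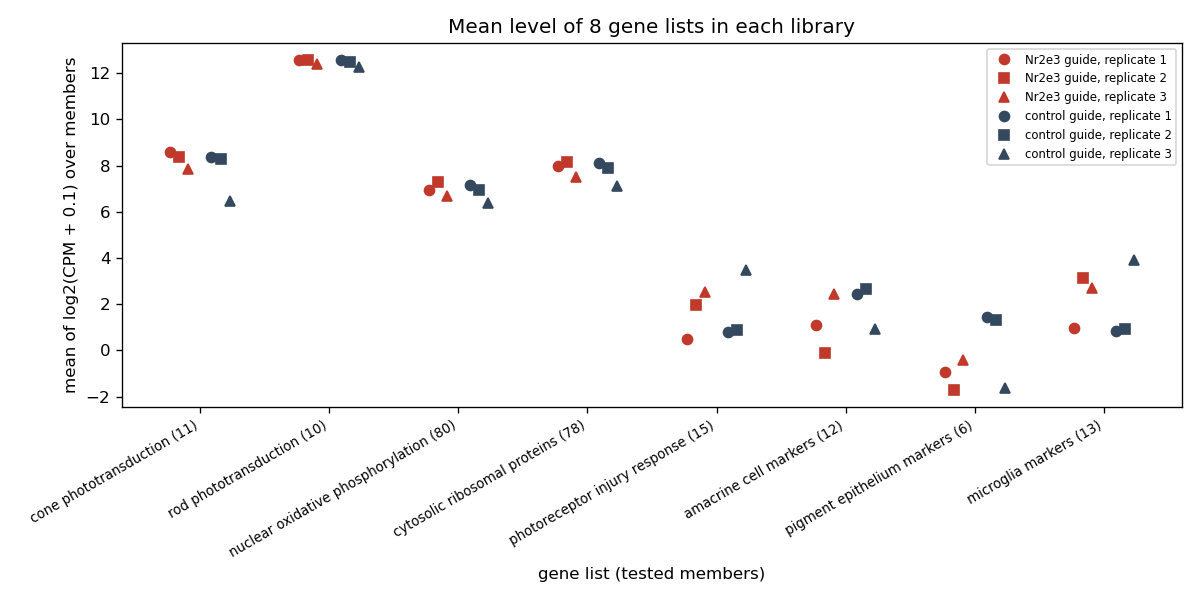
Mean of log2(CPM + 0.1) over the tested members of 8 gene lists in each library, with a marker per replicate, red for guide and grey-blue for control. Control replicate 3 has the highest mean for microglia markers (3.92) and photoreceptor injury genes (3.48) and the lowest for cone phototransduction (6.46), oxidative phosphorylation (6.38) and ribosomal proteins (7.13).

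Sex-linked transcripts matched the sex given for all 6 animals. Xist, expressed from the inactive X chromosome, was at 176 and 130 CPM in the 2 female guide libraries and 0.531 CPM in the male one, and at 0.0318, 0 and 0 CPM in the control libraries. The Y-linked Ddx3y was at 0 in both females, where 3 counts would correspond to 0.131 and 0.0883 CPM, and at 31.2 to 37.5 CPM in the males. Over all genes, Xist, Kdm6a and Ddx3x did not pass by edgeR (adjusted p = 0.143, 0.296 and 0.108), and these 3 of the 9 tested sex-linked genes were higher adjusted over the list alone.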

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

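The term for the replicate-3 libraries, leaving both of them out, robust estimation, DESeq2 with sex as a term or on males, and the names of the mitochondrially encoded list were tests chosen after the data were seen, as was following single genes only where the text names them. The use of the mean log2 fold change as each list's value was set while the alternatives were computed. All 59 called genes kept their sign with unadjusted p under 0.05 wherever they were tested (53 with a mean of at least 5 CPM), but by edgeR fewer passed again under designs with fewer libraries or more terms. None of the 59 overlapped between groups, so a kept sign was largely fixed in advance when libraries were left out or sex was a term. With sex as a term 6 of the 59 were called again by edgeR and 59 by DESeq2, and on males 0 and 56. Without 1 library edgeR called again 14, 21 and 17 (guide replicates 1, 2, 3) or 13, 15 and 56 (control replicates 1, 2, 3). With both replicate-3 libraries out 42 passed again. With sex as a term in edgeR, the fold is that of guide replicate 1, a library used to choose the 59, against the male controls. The median change of the size of the log2 fold change was 0.04, so calls under that term ended through wider error and fewer residual degrees of freedom, not smaller folds. Nr2e3 ranged from 0.27 to 0.43 on the log2 scale over 21 alternatives and did not pass in any of them. Kdm1b, Igfbp2 and Ppef1 passed in 20 of 21 alternatives each, the exception being males only by edgeR. Smug1 (adjusted p = 0.0468) missed the threshold with robust estimation (0.0503), and its adjusted p ranged from 9.67e-09 to 0.479 over all alternatives. Gm7616 ranged from 2.46 to 3.07, Gnat2 from 2.83 to 3.68 and Pde6c from 2.38 to 3.10. At this depth and spread, 2-fold changes were mostly out of reach, since edgeR recovered 7% of them in simulated data.

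Genes higher and lower, against 54 and 5, were 201 and 70 with DESeq2, 160 and 19 with limma-voom, 130 and 25 with no count filter, 6 and 0 with sex as a term, 0 and 0 on males (1752 at unadjusted p under 0.05), 125 and 147 with DESeq2 and sex, and 103 and 119 with DESeq2 on males. They were 16 and 0 at an adjusted p of 0.01, 83 and 8 at 0.1, and 32 and 1 against a 1.5-fold change. The replicate-3 term gave 8 lower. Leaving out 1 library gave 14 to 80 higher and 0 to 9 lower. DESeq2 also called more unchanged genes in the simulation. Called lists, against 4, numbered 0 with DESeq2, an estimated correlation or fry's test for 1 direction, 7 with no filter or both replicate-3 libraries out, 1 with a mean of at least 5 CPM, and 0 to 12 when 1 library was left out. Several lists passed camera's preset correlation only under an alternative. With sex as a term, which compares guide replicate 1 with the male controls, these were injury (-2.92, adjusted p = 0.0138), Muller glia (-1.20, 0.0138) and cone phototransduction (0.62, 0.0243). On males, with that guide animal alone, it was Muller glia (-1.22). With limma-voom they were Muller glia (-0.51, 0.0230) and microglia (1.07, 0.00813). With no filter they were crystallins (2.39e-08), cone phototransduction (0.0431) and immediate early genes (0.0333), the last also with a mean of at least 5 CPM (0.0103). With both replicate-3 libraries out they were Muller glia (-0.69), astrocyte (-2.14), bipolar (-0.50), microglia (1.43) and cone phototransduction (0.18), and with the replicate-3 term cone phototransduction (0.58) and immediate early genes (-0.34). These calls were not repeated with an estimated correlation. Leaving out the 50 most abundant genes from the library size moved nothing, because TMM rescales.

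The replicate block gave 31 higher and 1 lower, with 27 of the 59 called again. Under it camera called cone phototransduction (0.57, adjusted p = 0.0415) and immediate early genes (-0.43, 0.0352), and pigment epithelium no longer passed (0.0575). Deviations of same-numbered libraries correlated at 0.13, -0.14 and 0.03, which gave no sign of pairing over all genes, and not every library correlated best with its own number. These values cannot exclude a difference shared by the replicate-3 libraries alone.

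Direction changed mostly where neither value passed. The cause was not tested. The unfolded protein list (0.000286) became -0.00318 with DESeq2, -0.00335 with its size factors, -0.0273 with upper-quartile factors, -0.0293 with limma-voom, -0.683 on males, -0.0677 with a mean of at least 5 CPM, -0.272 with no filter, -0.0191 with the replicate block, -0.000515 with the replicate-3 term, -0.267 with sex as a term and -0.504 with both replicate-3 libraries out. With both of these out, C1qb became 1.44, Edn2 2.22, Stat3 0.40, glycolysis 0.0172, injury 0.458, microglia 1.43 and vascular -0.556. With limma-voom, C1qb became 0.853, Edn2 1.03, Stat3 0.249, glycolysis 0.0327, oxidative phosphorylation -0.00898, ribosomal -0.000884, injury 0.479, microglia 1.07 and vascular -0.263. On males, Ctss became -1.63, outer segment -0.000544, interferon -1.41, bipolar 0.0504, horizontal 0.0447, leukocyte -1.17, vascular -1.32 and crystallins -1.97. With sex as a term, Arr3 became 0.00613, Ctss -1.62, interferon -1.27, bipolar 0.0633, horizontal 0.0581, leukocyte -1.15, vascular -0.453 and crystallins -0.929. With a mean of at least 5 CPM, ribbon synapse became -0.0128, p53 0.0319 and interferon -0.259, and with no filter, outer segment -0.00199, p53 0.236 and vascular -1.30. With the replicate block, C1qb became 0.156, Edn2 0.207, microglia 0.368 and red blood cell 0.241. With the replicate-3 term, C1qb became 0.498, Edn2 0.740, other rod-enriched 0.000314, injury 0.217 and microglia 0.711. With upper-quartile factors, ribbon synapse became -0.00543 and outer segment -0.00867.

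Log2 values changed sign for some libraries left out, with ranges of -0.91 to 1.57 for C1qb, -0.43 to 2.21 for Ctss, -2.31 to 2.11 for Edn2 and -0.85 to 0.49 for Stat3. Mean list values ranged from -0.41 to 0.063 for bipolar, -0.19 to 0.043 for clock, -0.096 to 0.36 for ribosomal, -0.15 to 0.084 for glycolysis, -0.69 to 0.027 for horizontal, -0.72 to 0.088 for immediate early, -0.17 to 0.84 for leukocyte, -0.37 to 0.80 for interferon, -0.57 to 1.80 for microglia, -0.046 to 0.30 for oxidative phosphorylation, -0.045 to 0.012 for other rod-enriched, -0.043 to 0.14 for outer segment, -0.71 to 0.042 for p53, -1.71 to 1.43 for injury, -0.045 to 0.095 for ribbon synapse, -0.96 to 1.67 for red blood cell, -1.13 to 0.25 for ganglion, -0.0029 to 0.15 for rod phototransduction, -0.52 to 0.0034 for unfolded protein and -0.29 to 0.39 for vascular genes.

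Of the other values, 700 for named genes comprised 540 with the same direction and side of the threshold, 111 that no longer passed, 30 that newly passed and 19 of changed sign, each of these 19 uncalled in both. For lists, 481 stayed on their side, 34 no longer passed, 43 newly passed and 87 changed sign, 75 of them uncalled in both.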

Other observations

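All tests in this part were chosen after the result they bear on was seen, and bounds for the hypotheses on cone-expressed genes and on the other cone genes were reset after their values were known, as was the choice to leave sex-linked genes out of the test of sex. The relation between cone genes within a library was not described above. In guide libraries, Gnat2 was at 9.98 ± 1.68 times the level of the cone arrestin Arr3, against 0.699 ± 0.210 times in control libraries, and Pde6c at 1.40 ± 0.385 against 0.149 ± 0.0168 times (SD, n = 3 each). The groups do not overlap in either ratio, and 0.1 is the smallest exact two-sided permutation p that 3 against 3 allows. Among called genes not described above, Ephx2, soluble epoxide hydrolase, rose 2.94-fold (log2 SE 0.14, adjusted p = 0.00884), Pdha1, a subunit of pyruvate dehydrogenase, 2.96-fold (SE 0.14, adjusted p = 0.00913), Akr1b3, aldose reductase, 2.92-fold (SE 0.16, adjusted p = 0.0148) and Chd7, a chromatin remodeller, 2.17-fold (SE 0.15, adjusted p = 0.041).

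The first pattern is the set of 59 called genes. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many calls, the real one, and the highest of the others gave 0, with too few splits for a share under 0.05. Sex could contribute, because 2 guide animals are female and all control animals male. Over the 59, the male guide library shifted by a median 1.04 of the female shift (quartiles 0.972 and 1.10) and lay outside the controls in 59, and with sex as a term DESeq2 called 59 again and edgeR 6. That library was in the fit that chose the 59, none of which overlap between groups. Its place outside the controls was thus fixed, and these values do not test sex. Fits without that library called 20 genes, and over the 15 that are not Y-linked or in the sex-linked list the ratio was 0.982 (quartiles 0.912 and 1.04), with 15 outside. Among these 15, Fam185a, which is not one of the 59, shifted by 1.41 in the male against 4.07 in the females (ratio 0.347). For the other 14, all among the 59, the left-out library argues against sex as the whole cause, though the test rests on 1 male guide animal. Of the 59, 45 were called only with that animal included, so sex was not tested for them.

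The second pattern is Gnat2 and Pde6c high while most other cone phototransduction genes were not, with Pde6h (log2 fold change 1.97) and Gnb3 (0.44) as exceptions. More cones among the sorted guide cells would raise all of these genes. The other 9, Pde6h and Gnb3 included, had a median log2 fold change of -0.662 (SD 0.926 over genes, 7 of 9 negative). These 9 values belong to the pattern as it was defined, so they restate it and give no separate test. Of the 14 other cone-enriched genes, which did not define the pattern, 10 were negative (median -0.68). The 4 positive ones included Smug1 and Pygm. As a set these 14 genes did not rise, which argues against more cones as the whole cause. Few cones in control replicate 3 would end the difference without that library, but the log2 fold change of Gnat2 was then 2.83. Expression of these genes in guide-treated rods stays open as a hypothesis that counts of pooled cells did not test.

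The third pattern is control replicate 3, which stood apart from the other controls in microglia, injury, cone, ribosomal and amacrine genes. If it were a guide library with a wrong label, genes called without it would place it near the guide libraries. Over 89 such genes its median position was 0.0146 on a scale from the other controls (0) to the guide libraries (1), with quartiles of -0.198 and 0.325, which argues against that. Microglia and injury list means were high together in control replicate 3 (3.92 and 3.48), guide replicate 2 (3.13 and 1.98) and guide replicate 3 (2.71 and 2.52), and low in guide replicate 1 (0.955 and 0.509) and control replicates 1 (0.826 and 0.804) and 2 (0.936 and 0.905). A correlation was computed and then set aside because the libraries form separate sets, so no test of the relation is given. Guide replicate 3 shared part of the pattern. It and control replicate 3 had their group's lowest means for ribosomal (7.52 and 7.13) and oxidative phosphorylation genes (6.69 and 6.38). Their mitochondrial shares were also the lowest (1.31 and 1.27%). Amacrine genes went the other way, with guide replicate 3 the highest guide library (2.43). Guide replicate 2 also stood apart, at 122 on the first principal component (34.8% of variance), where the other libraries ran from -47.8 to -0.896. On the second (25.3%), control replicate 3 was the lowest (-93.6). Guide replicate 2 had 20309 genes with a count, against 22731 to 26600 in the others. Differences between animals in retinal injury or sorting purity, or a difference shared by the replicate-3 libraries, stay open and were not tested.

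A hypothesis was that the 54 higher genes may be genes that cones express in the control retina, which would put them low in control replicate 3. Their median log2 ratio of that library to the other controls was -0.165, at percentile 5.97 of 10000 random lists matched on level (random 5th percentile -0.173). This neither meets nor excludes the hypothesis.

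A further hypothesis, formed after adjacent called genes were noticed by eye, was that called genes lie beside each other in the genome. Within 100 kb of another called gene lay 8 of the 59, against a median of 0 and a 95th percentile of 4 in 10000 random lists matched on level, of which 0.2% held as many. The pairs were Elovl2 with Smim13, Gulo with Ephx2, LOC108168713 with A930031H19Rik, and Bcat1 with Gm26666. In each of the last pairs the genes overlap and can share reads. Counting only neighbours that do not overlap gave 4 genes, and 8.36% of random lists counted in that way held as many.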
